A study of Mus musculus with 8 samples.

How the data were processed

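The series holds 8 samples of mouse dendritic cells, called CD8-positive in the titles of the ATAC-seq samples. Per the labels, chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done for IRF3 after poly(I:C), for IRF5 after CpG oligonucleotide and for IRF9 after interferon-beta, each after 90 min of stimulation and in 2 samples. The other 2 samples are ATAC-seq libraries of unstimulated cells. ATAC-seq marks open chromatin by letting a transposase cut and tag accessible DNA in nuclei. The 2 ATAC-seq samples have processed files here, and the binding of IRF3, IRF5 and IRF9 was not analysed here. One label field calls the source splenic dendritic cells and another names a cell line. The labels also disagree on the unit of the poly(I:C) dose, which no value here depends on. Nothing in the labels says whether the replicates came from separate cultures, so the differences between them may be technical.

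Each ATAC-seq sample has its own list of peaks, with 1 entry per summit and a letter for each summit of a peak with several. The submitters' processing notes name Trimmomatic, BWA 0.7.17, Picard 2.8.1, HOMER 4.9.1, MACS2 and the mouse build mm10, without saying what each was used for. How reads were shifted for the transposase, whether duplicates or unreliable regions were removed and which threshold was set are not stated in the sources used here. All of these can change which weak peaks are listed. The layout of the deposited files is that of MACS2, and peaks were called on each sample by itself. The deposited fold enrichment is the ratio of reads at the summit to the local background of the same library, each with 1 added. The added 1 lowers the value most where the background is low, so fold enrichments of libraries of unlike depth are not strictly on the same scale. The deposited −log10 p and −log10 q measure how far the summit stands above that background, and the deposited score is the −log10 q times 10, reduced to a whole number. These are the authors' values for each peak and were used here only to describe, rank or filter peaks within a list. The lowest listed −log10 q was 3.00 in replicate 1 and 3.00 in replicate 2, as a cut-off at 3 would give. Peak numbers ran without gaps up to 50950 in replicate 1 and 58319 in replicate 2. In replicate 1, 13 summits had no position and were used as part of their peak. Peak names carry a different tag in each list, whose meaning is not given in the sources used here.

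Summits of the same peak were joined into 1 region that kept its highest score. Overlaps and tests were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Read numbers at each summit were worked out from the fold enrichment and the Poisson p, and the deposited −log10 p came back within 0.002 for 100% of the summits of both replicates. The background shared by the whole genome was 0.676 reads per position in replicate 1 and 1.28 in replicate 2, a ratio of 1.89 that equals the ratio of depths if both libraries were extended by the same length. The weakest listed summits held 7 reads in replicate 1 and 9 in replicate 2, so sites with fewer reads are absent from the lists. A missing peak therefore shows that a site was not detectable at this depth and threshold, not that it was closed.

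Gene positions came from the RefSeq annotation of GRCm38.p6, whose chromosomes are those of mm10. The table used here gives the start and end of each gene without its strand, so transcription start sites could not be told from gene ends. Before the data were examined, the plan was to use windows of 1 kb around transcription start sites; windows of 1 kb around either end of a gene were used in their place. A gene's ends are the outermost ends of all its transcripts, so a promoter can lie inside a gene, and exons, introns and untranslated regions were not assigned. A genome sequence was not used here, so the planned searches for interferon-stimulated response elements and other motifs were not run.

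The following choices were made before the data were examined: the tests, the 19 gene lists, the rule for named genes and most alternatives. A peak counted as shared if it overlapped a peak of the other replicate by at least 1 bp, and a shared region is the merged stretch of overlapping peaks that holds a peak of each replicate. Overlap and the share of regions at gene ends were set against 1000 circular shifts of the peaks along each chromosome (one-sided permutation tests). Gene lists were compared with the other protein-coding genes of the autosomes and X by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 19 lists. A region was placed by its centre, whereas a gene counted as having an accessible end when any part of a shared region reached within 1 kb of an end, so a few regions count as both end and distal. Fold enrichments printed for a gene are those of both replicates in its highest scoring shared end region. The number of shared regions 1 to 50 kb from the nearer gene end was compared with 10000 random lists of the same size matched on gene length in 10 strata (two-sided permutation test, adjusted in the same way). The lists hold 384 members (383 genes, since Tlr3 is in 2 lists); Mx1, Mx2 and Cxcl11 were left out because the annotation calls them transcribed pseudogenes. The genes named are the 3 members of each list with the highest scoring end peak, up to 2 members without a shared end peak in alphabetical order, 16 fixed genes, the 5 genes outside the lists with most distal regions and the 5 highest scoring regions. Of the genes this rule names, 2 are not reported here. Genes and regions are not replicates, so these p-values describe the 2 libraries. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only.

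The steps were tested on simulated data. Of lists simulated with 80% of members open, 83% were called higher. Of those with 10% open, 90% were called lower, against 1.17% of unchanged lists called either way. These simulations used 21631 genes, drawn regardless of position. The lists with 10% open had the sizes of the neuronal and housekeeping lists, 18 and 20 genes. Most lists called lower in the data were smaller, and real lists hold neighbouring genes, so these rates need not carry over. The alternatives tried were other overlap rules, stricter peak sets, other windows and distances, each replicate alone, 1 gene per 100 kb of each list, and random lists matched on gene length and number of neighbouring genes. The last 2, a count of regions anywhere in a gene and a count without an evenly spaced run of regions, alone or with 3 regions beside it, were chosen after seeing the data.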

Results

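Open chromatin was mapped by ATAC-seq in 2 samples of unstimulated mouse CD8-positive dendritic cells. They are taken here as the cross-presenting conventional dendritic cells called cDC1, and the labels leave open whether they were a cell line. The study's title names the choice of enhancers by IRF3, IRF5 and IRF9, transcription factors that act downstream of nucleic acid sensing and interferon receptors. The unstimulated maps show which sites were accessible before any stimulus, here near genes of lists fixed in advance. The target genes of these factors were not identified here. Replicate 1 had 50950 peak regions covering 8.71 Mb, and replicate 2 had 58319 covering 11.2 Mb. The authors' median fold enrichment was 7.0 in replicate 1 and 6.88 in replicate 2, and the median summit held 17 and 22 reads. Coordinates are those of mm10.

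The first comparison asked how far the accessible regions of the replicates coincide. The cells had 44365 shared accessible regions, 10.3 Mb in all, and they included the starts or ends of genes for sensing nucleic acids and for interferon signalling. Among them were Irf3 (chr7:44997563-44997714) and Irf9 (chr14:55603967-55604262), which encode 2 of the factors studied, and Tlr9 (chr9:106222488-106222703), the receptor for CpG DNA. The Irf3 peak had a fold enrichment of 10.0 in replicate 1 and 8.34 in replicate 2, the Irf9 peak 8.54 and 9.25, and the Tlr9 peak 10.3 and 9.44. Irf5 had no shared region within 1 kb of an end, and its nearest shared region was centred 1357 bp inside the gene.

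Of the peaks of replicate 1, 90.0% overlapped a peak of replicate 2, and 76.5% of the peaks of replicate 2 overlapped one of replicate 1. Circular shifts gave means of 0.835% and 0.723%, and the highest of 1000 shifts reached 1.04% and 0.888% (one-sided permutation p = 0.001 for each, the smallest these shifts can give). Across the shared regions the authors' scores had a Spearman rho of 0.74 between replicates, a value across regions, which are not independent replicates. The share rose with the score. In the lowest decile of each list 70.6% of the peaks of replicate 1 and 36.2% of those of replicate 2 were shared, and in the highest 100% and 99.9%.

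**Figure D1:**
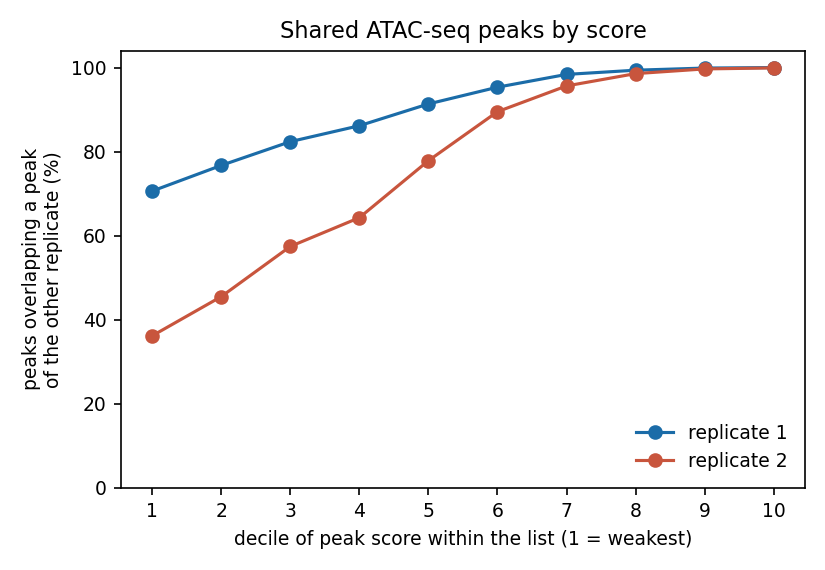
Percentage of the peaks of each ATAC-seq replicate that overlap a peak of the other replicate (y axis), by decile of the authors' peak score within the list (x axis, 1 is the weakest). The points of replicate 2 start at 36.2% and those of replicate 1 at 70.6%, and both reach at least 99.9% in the highest decile.

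Regions found in 1 replicate were weaker than shared ones and lay less often at gene ends. Batf3, which encodes a transcription factor required for cDC1 development, had such a site: a peak at its end in replicate 2 with a fold enrichment of 3.63 and none in replicate 1. Replicate 1 had 5086 peaks without a partner, with a median score percentile of 18.7 against 54.5 for its shared peaks. Replicate 2 had 13732, with a median percentile of 19.9 against 61.2. Their summits held medians of 11 and 15 reads, against 17 and 25 at shared summits. Within 1 kb of a coding gene end lay 20.3% of the peaks of replicate 1 alone and 18.3% of those of replicate 2 alone, against 28.3% of shared regions (Fisher's exact test, two-sided, p = 1.5e-35 and p = 1.7e-125). With a reciprocal overlap of 50% as the rule for sharing, the direction turned for replicate 1, where 30.0% of the peaks without a partner lay at gene ends.

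The next comparison asked where the shared regions lie relative to genes. They were concentrated at the ends of coding genes: 12534 of 44328 regions on the autosomes and X (28.3%) had their centre within 1 kb of an end, against 3.08% after shifting (ratio 9.17, one-sided permutation p = 0.001, the smallest the shifts can give). A further 17456 regions (39.4%) lay inside genes, against 38.3% after shifting, and 14338 (32.3%) lay between genes, against 58.6%. A gene was counted as having an accessible end when any part of a shared region reached within 1 kb of an end, which 10348 of 21631 coding genes did (47.8%). Tbp, Eef2 and Vcp, which encode the TATA-binding protein, an elongation factor and an ATPase used by all cells, had end peaks with fold enrichments from 8.72 to 11.2. Actb had none by this measure, and its nearest shared region was centred 1242 bp inside the annotated gene. Eef2 had 2 shared regions at its ends. The highest scoring of them lay wholly outside the annotated gene, centred 342 bp from its end, so it may belong to a neighbouring gene.

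The gene lists fixed in advance asked which response programmes were accessible before stimulation. Interferon-stimulated genes, genes for nucleic acid sensing and interferon receptor signalling, NF-kB feedback and maturation genes, antigen presentation genes and housekeeping genes had accessible ends more often than other genes. The 18 listed genes encoding type I and III interferons had them less often. That call was lost in lists matched on neighbouring genes and at 1 gene per 100 kb. Of 39 interferon-stimulated genes 31 had a shared region at an end (79.5%, 95% interval 63.5 to 90.7), against 47.8% of the other coding genes (adjusted p = 0.000691, Fisher's exact test). The strongest were Gbp3, a guanylate-binding GTPase, at chr3:142560443-142560684 with fold enrichments of 13.6 and 13.8, Ifit2, an antiviral RNA-binding protein, at chr19:34550502-34550739 with 11 and 14.5, and Stat2, a subunit of the interferon-activated factor ISGF3, at chr10:128270278-128270578 with 12 and 11.7. Ifih1, the gene of the RNA sensor MDA5, had 10.7 and 10.4. Cmpk2 and Ddx58 were among the 8 members without one; the nearest shared region to Ddx58, the gene of the RNA sensor RIG-I, was 1372 bp from its end, whereas that to Cmpk2 was 563286 bp away. With the better-scoring 50% of each list the share of interferon-stimulated genes was 48.7%, against 34.8% of other genes, and no longer passed (adjusted p = 0.123, Fisher's exact test).

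Of 33 genes of nucleic acid sensing and interferon receptor signalling, 25 had an accessible end (75.8%, adjusted p = 0.00417, Fisher's exact test). Tlr4, the endotoxin receptor, had fold enrichments of 11.2 and 14.1, Ifnar1, a chain of the type I interferon receptor, 10.0 and 11.4, and Ticam1, the adaptor of Tlr3, 8.84 and 9.58. Ifnar2, the other chain, had 7.07 and 10.7, and Tlr3, the receptor for double-stranded RNA, 5.21 and 5.80. Ikbke and Irf5 were among the 8 members without a shared region at an end. Of 25 NF-kB feedback and maturation genes 21 had one (84.0%, adjusted p = 0.00243, Fisher's exact test), led by Tnfaip3, an inhibitor of NF-kB signalling, with 11.2 and 11.7, Cd274, the gene of the ligand PD-L1, with 12.5 and 10.2, and Relb with 9.51 and 9.37. Ccr7, a receptor for migration to lymph nodes, and Nfkb2 had none. Of 22 antigen presentation genes 20 had one (90.9%, adjusted p = 0.000691, Fisher's exact test), among them the class I genes H2-K1 with 9.24 and 10.8 and H2-D1 with 9.49 and 8.20, and H2-DMb1, which helps to load class II molecules, with 7.97 and 9.54. The exceptions were Cd1d1 and H2-Oa. With a window of 500 bp NF-kB and maturation genes stood at 64.0%, against 44.3% of other genes, and no longer passed (adjusted p = 0.0921, Fisher's exact test).

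Among the 18 type I and III interferon genes 2 had an accessible end, Ifnz and Ifna14 (11.1%, 95% interval 1.38 to 34.7, adjusted p = 0.00417, Fisher's exact test). Ifnz had fold enrichments of 6.39 and 6.18, and Ifna14 had 5.13 and 4.75. The Ifna14 region was near the floor of the lists. It held 8 reads at its summit in replicate 1 and 10 in replicate 2, where the fewest listed were 7 and 9. The Ifnz region belongs to the evenly spaced run described with the interferon cluster, and without that run 1 of 18 had an accessible end (5.56%, adjusted p = 0.00114, Fisher's exact test). Of the 12 coding genes under the run, the list holds Ifnz but none of the predicted genes. The regions of the run were centred 24 to 637 bp from a coding gene end, so the share describes the listed genes and not the whole cluster. Ifnb1, Ifna1 and Ifna12 had none, and the nearest shared region was 6214 bp from Ifnb1, 14153 bp from Ifna1 and 30585 bp from Ifna12. Against random lists matched on gene length and neighbouring genes, chosen after seeing the data, the interferon genes no longer passed (adjusted p = 0.187, permutation test), nor did they at 1 gene per 100 kb (20.0%, adjusted p = 0.422, Fisher's exact test). Inflammatory cytokine and chemokine genes were not told apart from other genes, with 12 of 27 (44.4%, adjusted p = 0.848, Fisher's exact test). Ccl22 had fold enrichments of 12.5 and 12.2, Il18 8.89 and 11.5, Tnf 10.7 and 10.1, Cxcl10 8.06 and 5.54 and Il12b, a subunit of interleukin-12, 6.17 and 9.01, while Ccl3 and Ccl4 had no shared end region. The cDC1 identity genes stood at 18 of 28 (64.3%, 95% interval 44.1 to 81.4), short of the threshold (adjusted p = 0.122, Fisher's exact test). Itgax, the gene of CD11c, had 7.86 and 7.19, the cytokine receptor gene Flt3 12.4 and 13.4, Ifi205 10.3 and 11.5, and Irf8, a regulator of cDC1 fate, 5.45 and 5.12. Batf3 and Btla were among the 10 without a shared end region. The cDC1 list passed with a window of 2 kb (78.6% against 52.3% of other genes, adjusted p = 0.0132) and without replicate 1 (78.6%, adjusted p = 0.00731, Fisher's exact tests).

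Genes of several other blood cells and tissues were less often accessible. Ends were open less often than in other genes for neutrophil genes (1 of 15, adjusted p = 0.00417, Fisher's exact test), erythroid genes (1 of 14, 0.00488), hepatocyte genes (2 of 16, 0.00992), NK cell genes (1 of 12, 0.0131), fibroblast and stromal genes (2 of 15, 0.0134), neuronal genes (3 of 18, 0.0134) and T cell genes (3 of 16, 0.0338). The open members were Cebpe of the neutrophil list, Hbb-bs, Apoa2 and Apoa1, Klre1, Twist2 and Col1a1, Tubb3, Syn1 and Eno2, and Cd5, Cd28 and Cd3d. Apoa2 had fold enrichments of 9.56 and 10.9 in a region centred 1072 bp from its end, and Cd5 had 9.29 and 10.9. Others were at the floor of the lists: Klre1 had 7 reads at its summit in replicate 1 and Cd3d had 9 in replicate 2, the fewest of any listed summit there. The cDC2 list (5 of 16, led by Irf4, Notch2 and Clec4a2), the plasmacytoid dendritic cell list (5 of 16, led by Lair1, Siglech and Ly6c2), the B cell list (4 of 14, led by Bank1, Fcrla and Ebf1) and the macrophage and monocyte list (11 of 20, among them Maf and C1qa) did not pass the test, with adjusted p of 0.242, 0.242, 0.234 and 0.692. Housekeeping genes were open in 17 of 20 cases (85.0%, adjusted p = 0.00417, Fisher's exact test). The T cell call was lost with windows of 500 bp (adjusted p = 0.0651) and 2 kb (0.0617) and with the union of both replicates (0.0605), the NK cell call with 2 kb (0.339), and the hepatocyte call with the better-scoring 50% of each list (0.0999, Fisher's exact tests). Counting regions anywhere in a gene, chosen after seeing the data, ended the NK cell (33.3%, adjusted p = 0.122) and neuronal (38.9%, 0.132) calls and put T cell genes at 62.5%, above the 60.0% of other genes (adjusted p = 1, Fisher's exact tests). Without replicate 1 the T cell list stood at 25% (adjusted p = 0.065) and the erythroid list at 21.4% (0.05004), both no longer past the threshold of Fisher's exact test.

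**Figure D2:**
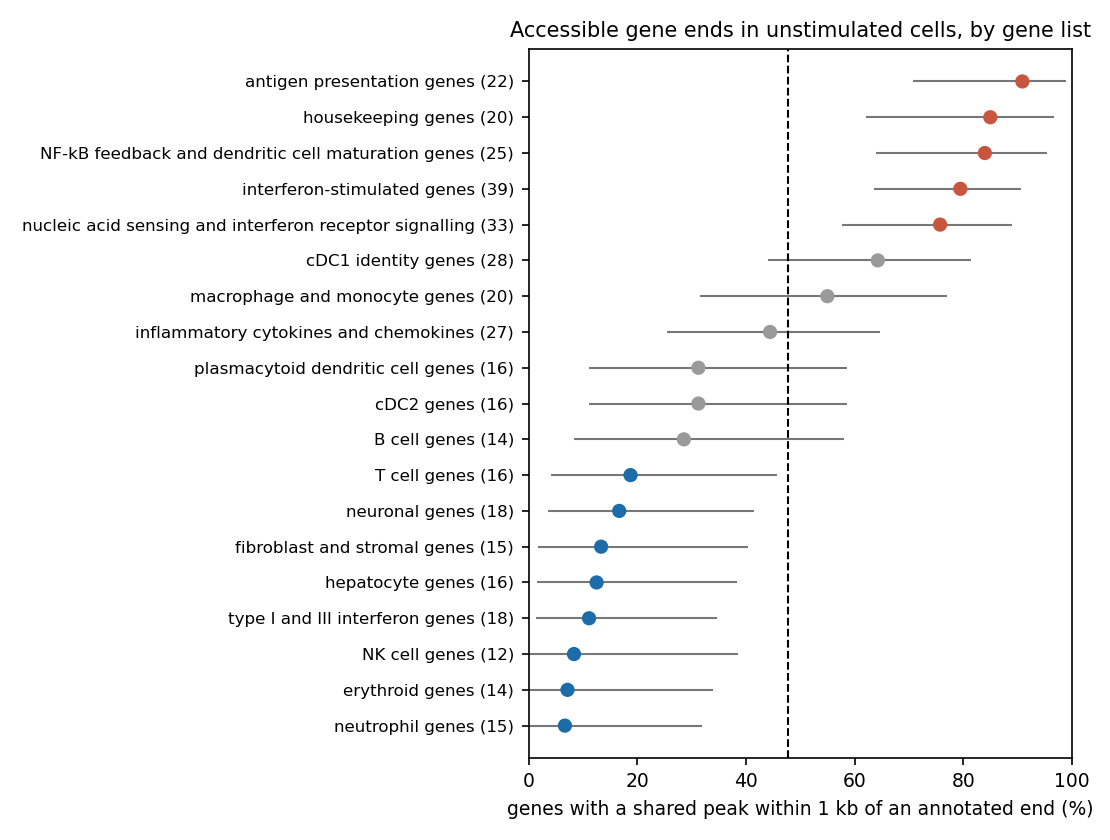
Percentage of genes in each list with a shared ATAC-seq region within 1 kb of an annotated gene end (points), with exact 95% intervals (lines); the number of genes is in brackets and the dashed line is the 47.8% of all coding genes. Red lists were above and blue lists below the other genes at an adjusted p under 0.05, and grey lists passed neither way; antigen presentation genes stand highest at 90.9% and neutrophil genes lowest at 6.67%.

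The last comparison asked how many accessible regions lay 1 to 50 kb from an end of these genes, called distal here. They can include enhancers, but regions at the ends of neighbouring genes were counted as well. Of all shared regions 28.3% lay within 1 kb of a coding gene end. Only the alternative that gave each region to its nearest gene end left those out. Antigen presentation, cDC1 identity, NF-kB and maturation, housekeeping, inflammatory and nucleic acid sensing genes had more shared regions 1 to 50 kb from an end than genes of like length, as had interferon genes through an evenly spaced run of regions in their cluster. Antigen presentation genes had a mean of 12 per gene, against 4.64 in matched random lists. The cDC1 identity genes had 8.46 against 4.66, NF-kB and maturation genes 8.08 against 4.60 and housekeeping genes 8.40 against 4.53 (adjusted p = 0.00095 for each of these 4 lists, two-sided permutation test; unadjusted p = 0.0002, the smallest that 10000 lists can give). Batf3 had 22 such regions, Flt3 had 11 and Irf8 9. Inflammatory genes had a mean of 7.07 against 4.44 (adjusted p = 0.0076, permutation test), with 17 around Tnf and 12 around Ccl22. Nucleic acid sensing genes had 6.55 against 4.66 (adjusted p = 0.0266, permutation test), with 14 around Ifnar1. The inflammatory call was lost within 20 kb (adjusted p = 0.0689), the sensing call within 100 kb (0.0718) and the housekeeping call when each region was given to its nearest gene end (0.12, permutation tests). With the better-scoring 50% of each list the NF-kB (adjusted p = 0.0503), sensing (0.0503) and inflammatory (0.0751) calls were lost together (permutation tests).

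Interferon genes had a mean of 5.28 distal regions against 2.19 in matched lists (adjusted p = 0.0125, permutation test), and Ifnb1 had 4. Without the 12 regions of the evenly spaced run, an alternative chosen after seeing the data, the mean was 3.22 and the call was lost (adjusted p = 0.365, permutation test), and the number around Ifnz went from 14 to 3. Those 3 lie beside the run with a like spacing; without them as well, also chosen after seeing the data, the mean was 3.06 (adjusted p = 0.407, permutation test) and Ifnz had 0. The interferon call was also lost within 20 kb (1.72, adjusted p = 0.171) and when each region was given to its nearest gene end (0.611, 0.12, permutation tests). Interferon-stimulated genes had 5.95 against 4.59, short of the threshold (adjusted p = 0.0771, permutation test), with 16 around Stat2 and 11 around Ifit2. Fibroblast and stromal genes had fewer, 1.87 against 4.77 (adjusted p = 0.00684), as had hepatocyte genes, 2.5 against 4.74 (adjusted p = 0.0443, permutation tests). The cDC2, plasmacytoid, B cell, T cell, NK cell, macrophage and monocyte, neutrophil, erythroid and neuronal lists, with means from 3.89 to 5.81, did not pass the test. When each region was given to its nearest gene end, cDC2 genes (2.5, adjusted p = 0.0261) and macrophage and monocyte genes (1.85, 0.0261) passed as higher and neuronal genes (0.389, 0.0247) as lower (permutation tests). Outside all lists the most distal regions were around Arhgef10 (24), Pnkd (23), Lmna, Nup93 and Fgd3 (22 each). Neighbouring members of a list share regions, and the 18 interferon genes came down to 5 at 1 gene per 100 kb, where the call was lost (mean 5.80, adjusted p = 0.248, permutation test). In lists matched also on neighbouring genes, the adjusted p of the permutation test was 0.0897 for interferon genes, 0.0898 for fibroblast and stromal genes and 0.153 for hepatocyte genes, so none of these 3 calls held, while neutrophil genes passed as higher (5.53 against 3.24, adjusted p = 0.0369). The hepatocyte call was also lost without replicate 1 (mean 3.69, adjusted p = 0.106), within 100 kb (5.19, 0.0718), with the better-scoring 50% of each list (1.19, 0.0874) and when each region was given to its nearest gene end (0.312, 0.0984, permutation tests).

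**Figure D3:**
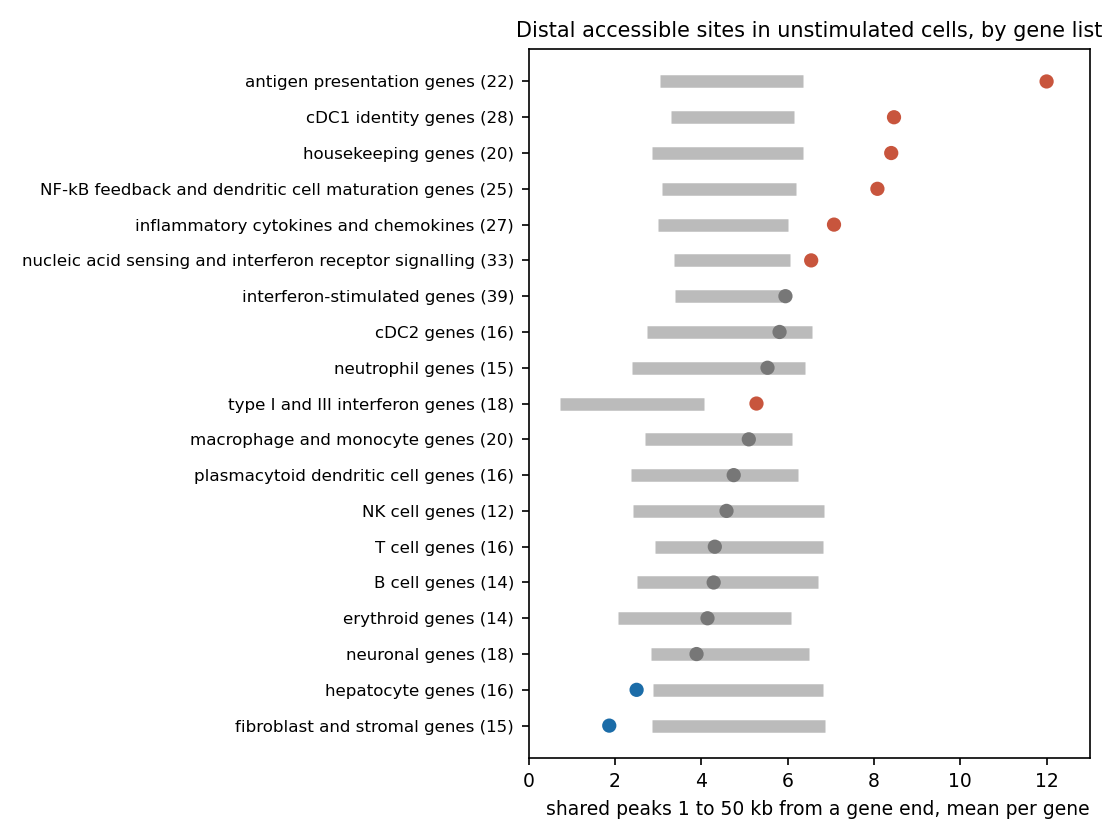
Mean number of shared ATAC-seq regions 1 to 50 kb from the nearer gene end, per gene, for each list (points), with the middle 95% of 10000 random lists matched on gene length (bars). Red points were above and blue points below at an adjusted p under 0.05, and grey points passed neither way; antigen presentation genes lie at 12 and cDC1 identity genes at 8.46.

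The type I interferon gene cluster on chromosome 4 held 15 of the 18 interferon genes, from Ifnb1 to Ifne, between 88522025 and 88880201. It contained 26 shared regions. Of these, 12 formed an evenly spaced run at chr4:88773724-88806206, with 2891 to 2947 bp between neighbours, over 12 annotated coding genes that include Ifnz and a series of predicted genes from Gm13272 to Gm13290. Their fold enrichments ran from 5.18 to 8.59 in replicate 1 and from 5.32 to 10.1 in replicate 2. Before the run lay 3 more shared regions with centres 2971 and 2937 bp apart, the last of them centred 10258 bp from the first of the run.

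**Figure D4:**
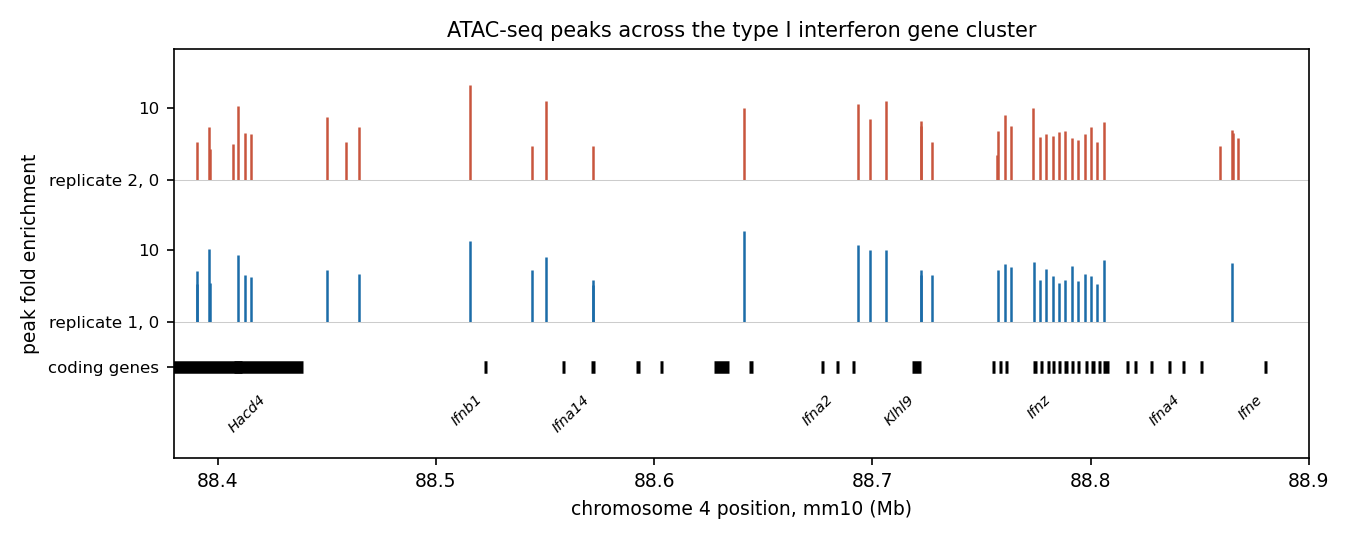
Fold enrichment of each ATAC-seq peak of replicate 1 (blue) and replicate 2 (red) across the type I interferon gene cluster (x axis, position on chromosome 4 in Mb), with coding genes as black bars; each replicate has its own zero line. The evenly spaced run of 12 shared regions lies around Ifnz, and the nearest shared region to Ifnb1 is 6214 bp from the gene.

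The 5 highest scoring shared regions lay away from gene ends. They were chr6:103649032-103649313 inside Chl1, chr13:77438882-77439075 inside 2210408I21Rik, and chr12:3109848-3110141, chr2:69355515-69355689 and chr9:35305203-35305612, which were in no coding gene. Their fold enrichments ran from 23.7 to 40.8, against 4.39 to 14.5 at the named genes with an open end. Of the 50 highest scoring regions 2 were at a gene end (4.0%), against 358 of the next 1000 (35.8%). Reads piling up at one place could also give such regions, so whether they are open sites stays undecided here.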

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

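The tests of the evenly spaced run, of the highest scoring regions and of gene density were chosen only after those results were seen. No biological explanation was tested, since the files hold a single group.

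Several signals lay outside the comparisons. Of 408 annotated tRNA genes 166 (40.7%) had a shared region within 1 kb of an end. Peaks on the mitochondrial genome numbered 5 in replicate 1 and 4 in replicate 2. Chromosome Y had 38 peak regions in replicate 1 and 39 in replicate 2.

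The 12 evenly spaced shared regions in the interferon gene cluster, around Ifnz, stood out because tandem copies of a sequence would give such spacing. If reads were placed at random among near-identical copies, their numbers should vary no more than Poisson draws. The variance over the mean of the summit reads was 0.387 in replicate 1 and 0.589 in replicate 2, inside the middle 95% of Poisson draws in both, so random placement may account for the even heights, but 12 copies that are equally open would look alike. More copies in these cells than in the reference would raise the local background: its median lay at percentile 92.7 of matched sets of shared regions in replicate 1 and 99.3 in replicate 2, both above the matched median but only replicate 2 beyond the middle 95%, so extra copies and chance cannot be told apart here. How many of the copies are open therefore stays open, since the mapping quality of the reads was not used here.

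The highest scoring regions stood out because few lay at gene ends, 4.0% of the 50 highest against 35.8% of the next 1000. These shares restate the pattern and say nothing about its cause. Reads of repeated or mitochondrial-like sequence piling up at one place could produce it. That explanation predicted a higher local background, which was lower instead, 1.51 against 1.76 reads in replicate 1 and 2.36 against 2.96 in replicate 2. A narrow pile-up need not raise the surrounding background, so this does not exclude it. Neither the genome sequence nor a list of unreliable regions was used here. The explanation and a set of very open distal sites were therefore not told apart.

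Gene density around the genes was weighed for the gene lists, because open regions gather where genes are dense. Against 10000 lists matched on gene length and number of neighbouring genes, the interferon-stimulated genes lay at percentile 99.9 for accessible ends and the cDC1 identity genes at percentile 100 for distal regions. Gene density as measured here therefore does not account for either pattern. Membership of generally active genes, which housekeeping genes share at 85.0%, was not tested as an explanation and remains open.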

How the results depend on the processing

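The tests with 1 gene per 100 kb, matching on neighbours, regions anywhere in a gene and no evenly spaced run, alone or with 3 regions beside it, were chosen only after the results were seen; the others were planned. No paired analysis was possible because a single group has files here. The planned motif results and their alternatives were not run, since no genome sequence was used, and overlap and rank agreement cannot be computed without a replicate. Of the list results for gene ends under each setting, 188 kept their direction and side of the threshold. In the same direction 13 lost their call and 4 gained one, and 4 changed direction. For distal regions 155 kept both, 18 lost their call and 6 gained one in the same direction, and 11 changed direction. The share of peaks shared ran from 79.3% to 90.0% in replicate 1 and from 69.3% to 82.1% in replicate 2, and the share at gene ends from 23.0% to 33.8%. Depth sets the floor of the lists, 7 reads at a summit in replicate 1 and 9 in replicate 2. The cause of the changes below was not tested.

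Rank agreement was 0.80 by width in place of score. With a reciprocal overlap of 50%, the gene-end share of peaks of replicate 1 alone turned to 30.0%. Gene ends: cDC1 identity genes passed with a 2 kb window (78.6%), the union of both replicates (82.1%) and regions anywhere in the gene (96.4%), and ranged from 67.9% to 78.6% with a replicate left out, passing without replicate 1. Interferon-stimulated genes fell to 48.7% with the better-scoring 50% of each list. Interferon genes lost their call at 1 gene per 100 kb (20.0%) and matched on length and neighbours (11.1%). With regions anywhere in the gene 5 lists were lower, and uncalled or lost lists turned: plasmacytoid 68.8%, T cell 62.5%, macrophage and monocyte 60.0%. Matched on neighbours, inflammatory genes (44.4%) turned, uncalled. Without replicate 1 the T cell (25%) and erythroid (21.4%) calls were lost.

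Distal regions: interferon genes lost their call within 20 kb (1.72), by nearest gene end (0.611), at 1 gene per 100 kb (5.80), matched on neighbours (5.28) and without the evenly spaced run, alone (3.22) or with the regions beside it (3.06). Hepatocyte genes lost theirs within 100 kb (5.19), with the better-scoring 50% (1.19), by nearest gene end (0.312) and matched on neighbours (2.5). Interferon-stimulated genes passed with the better-scoring 50% (3.10) and at 1 gene per 100 kb (6.22). Lists lower than matched lists numbered 1 within 100 kb, 1 with the better-scoring 50%, 1 to 2 with a replicate left out (hepatocyte genes, 3.69, adjusted p = 0.106 without replicate 1) and 0 matched on neighbours by the permutation test (0 also at an unadjusted p under 0.05). Some uncalled lists changed sides. Within 20 kb these were plasmacytoid 1.75, B cell 2.36 and erythroid 1.71, and within 100 kb B cell 8.57 and T cell 8.69. With the better-scoring 50% they were B cell 2.21 and NK cell 1.83. The erythroid list also turned by nearest end (0.143), at 1 gene per 100 kb (4.17) and matched on neighbours (4.14). The NK cell list also turned in 1 of the 2 settings with a replicate left out (means 5.08 and 6.42).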

Other observations

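The gene families below were chosen only after the data were seen, and their values are given without a test.

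Large gene families of other tissues were almost without accessible ends. Of 1110 olfactory receptor genes 17 (1.53%) had a shared region within 1 kb of an end, and of 355 vomeronasal receptor genes 3 (0.845%). Stretches of at least 1 Mb without a peak of either replicate numbered 363. Mapping quality was not used here, so stretches where reads could not be placed uniquely may be among them. Of all 363, the stretch with most coding genes outside these receptor families was chr8:20882517-22006575. It held 45 genes that include many alpha-defensins, antimicrobial peptides of the gut. Another, chr4:60020490-62177405, held 22 coding genes, most of them for major urinary proteins. By contrast, 81 of 97 ribosomal protein genes (83.5%) had an accessible end. Among interferon-inducible families, 9 of 13 IFI200 genes and 6 of 10 guanylate-binding protein genes had one, and 2 of 9 SLFN genes.

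Noncoding genes differed by class. Away from coding genes, by more than 5 kb, 97 of 300 tRNA genes (32.3%) had a shared region at an end. At the same distance the shares were 10.5% of 8852 lncRNA genes, 3.96% of 809 miRNA genes, 6.0% of 850 snRNA genes, 2.44% of 1064 snoRNA genes and 3.15% of 8443 pseudogenes. Over all positions they were 18.7%, 10.7%, 8.67%, 6.72% and 3.91% in the same order. Among the V segments of antigen receptors 5 of 394 had one (1.27%).

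The interferon-stimulated neighbours Rsad2 and Cmpk2 lay in a stretch of 2.31 Mb without a peak in either replicate, chr12:26235875-28547049, together with Rnf144a and Sox11. An evenly spaced run like that of the interferon cluster was found at chr6:47654899-47685697, with 8 shared regions at a median spacing of 4335 bp over 6 predicted genes.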
